A study of Arabidopsis thaliana with 2 samples.

How the data were processed

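The study held 2 libraries of Arabidopsis thaliana, 1 of DNA from a chromatin immunoprecipitation with an antibody against GFP and 1 of input DNA. Both came from whole plants of the prr5 mutant with FLAG-PRR5-GFP under the PRR5 promoter. Per the labels' protocols, plants grew for 18 days on MS medium with 2% sucrose and 0.3% gellan gum in 12 h light and 12 h dark and were fixed 10 h after the light came on, nuclei were sonicated, and libraries were made with an Illumina ChIP-Seq kit. Samples were grouped by these labels, with 1 library per group.

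The data used here were 1 list of 8983 regions that the authors called in the ChIP DNA over the input DNA. Per the file headers, reads were mapped to TAIR9, the build that the submitters' processing notes also name; the aligner, the caller and their filters are not given in the sources used here. For each region the deposited list gave its start and end, its length in bp, a false discovery rate in percent of the ChIP relative to the input, and whole-number counts of all, forward and reverse reads. These deposited counts are not normalised, and the file headers do not say which library they are from. The false discovery rates are the authors' own values and were used only to rank or filter regions within the list, with ties ranked by reads. The deposited list has regions at every false discovery rate from 0 to 100%, so it is not a list filtered at a usual threshold. Regions were called on 1 ChIP and 1 input, so neither the spread between plants nor that between libraries can be given. The depth of the libraries is unknown beyond the 5112270 reads in regions. Intervals of reads are exact 95% Poisson intervals and those of shares 95% Clopper-Pearson intervals, and both cover counting error only. Those of reads treat reads as independent molecules, which reads copied in PCR are not, so they can be too narrow even for counting error.

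Region centres were set beside the genes of the RefSeq table of TAIR10.1, which was used for gene names and for which genes lie next to a region. The table is of another build than the list, so none of its coordinates are printed. As a check, the regions ranked lowest were shifted in steps of 100 bp by up to 3 kb either way in 15 blocks, 3 per chromosome, to find the shift with the fewest centres within 400 bp outside a gene. The lowest share was at no shift in 13 of the 15 blocks. The exceptions were the middle block of chromosome 2 and the first block of chromosome 4, and the last block of each of these chromosomes was at no shift. When the same centres were moved by 700 bp, 14 of 15 blocks gave the shift back within 200 bp. This follows largely from the scan itself and is not an independent check.

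A gene was assigned a region whose centre lay in it or within 1 kb of either end. The design fixed before the data were examined asked for 1 kb upstream of the transcription start, but the gene strand was not used here, so both ends were treated alike. With this rule 6753 regions had at least 1 protein-coding gene, 1835 of them 2 or more, and 2230 (24.8%) had none. The other genes of such a region are named in the report but not in the closing part, and the assay does not tell which gene it acts on. Of 217 members of the 11 gene lists, all 217 loci were matched; 209 list symbols were in the table, and genes among the other 8 are given by locus. Motifs in regions, and ChIP to input ratios per region, were planned but not analysed here, since no genome sequence or input count per region was used.

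The positions of region centres were compared with 1000 random placements of the regions on their own chromosomes (two-sided empirical p). Gene lists written before the data were examined (clock, flowering time, light signalling and hypocotyl growth, B-box zinc finger, cold response, abscisic acid, photosynthesis and chlorophyll, phenylpropanoid and flavonoid, auxin and gibberellin, starch metabolism, reference genes) were tested against 27444 protein-coding genes with a one-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 11 lists, with 0.05 as the threshold. Transcription factor genes were the 1063 whose RefSeq symbol or synonyms name a transcription factor family. The genes named were fixed by rule before the data were examined: those at the 10 regions ranked highest, the next 10 transcription factor genes, the 30 list members with the best regions, all clock members and PRR5. Other list members, and all genes and regions named in the closing part, were chosen after their values were seen.

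Alternatives fixed beforehand were the 4491 and the 2245 regions with the lowest false discovery rates, merging of overlapping regions, any overlap in place of the centre, all annotated genes, and a background of transcription factor genes. Alternatives chosen after seeing the data were regions at a false discovery rate of 5% or less, 500 bp and 3 kb beside genes, placement within 20 kb of each region, only regions outside genes, the nearest gene only, and 10000 random lists matched on gene length and on the space to both neighbouring genes.

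The tests were tried on simulated data. With 28% of genes given a region at random, 1% of 100 sets of 11 lists held a list that passed, and of lists with 65% of members near a region 91.3% passed. These lists were random genes that got regions independently, whereas in the data 1835 regions had 2 or more genes. The rates therefore need not hold for the real lists, some of which hold neighbouring genes. Of 40 sets of 8983 randomly placed regions none was called, and all 40 were when 5% of the regions were moved beside genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with random seed 20.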

Results

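Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the binding sites of PRR5 (PSEUDO-RESPONSE REGULATOR 5), a transcriptional repressor of the plant circadian clock, along the Arabidopsis thaliana genome. The plants were prr5 mutants that carried FLAG-PRR5-GFP, a doubly tagged PRR5 protein, under the PRR5 promoter. Whole plants were grown for 18 days in cycles of 12 h light and 12 h dark and taken 10 h after the light came on. There were 2 groups with 1 library each: DNA pulled down with an antibody against GFP, and the input DNA of such plants. The deposited list held 8983 regions called in the ChIP over the input on chromosomes 1 to 5, with 5112270 reads in the regions altogether; the read totals of the libraries are not given in the sources used here. With 1 library per group there was no replicate check, and every test takes regions or genes as its units and describes this pair of libraries only. Positions are those of the deposited list on TAIR9, and genes are named from the RefSeq table of TAIR10.1.

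Of the 10 regions ranked highest by false discovery rate and reads, 5 lay at genes of the clock or had one as the nearest gene. The region with the most reads, chromosome 5 from 8359855 to 8360011, held 26570 reads (95% Poisson interval 26251.5 to 26891.4, counting error only). It lay more than 1 kb from any protein-coding gene, and the nearest was PRR5 (AT5G24470), the tagged gene. The plants carried a transgene with the PRR5 promoter, so reads at PRR5 can come from the native locus or the transgene. The region ranked second, with 18796 reads (18528 to 19067) at chromosome 3 from 3923448 to 3923596, lay in LNK3 (AT3G12320), a night light-inducible and clock-regulated gene, and also within 1 kb of BUG22 (AT3G12300). GI (AT1G22770), which acts in the clock and in photoperiodic flowering, had a region beside it at chromosome 1 from 8060969 to 8061101 with 13358 reads (13132 to 13587). PRR9 (AT2G46790), a relative of PRR5, had 12486 reads (12268 to 12707) at chromosome 2 from 19232401 to 19232542, a region that also lay within 1 kb of AT2G46780. CCA1 (AT2G46830), a morning-expressed MYB factor of the clock, had 10492 reads (10292 to 10695) at chromosome 2 from 19245314 to 19245462, also within 1 kb of PSI-P (AT2G46820).

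The other 5 of the 10 regions ranked highest lay elsewhere. TCP9 (AT2G45680), a TCP-domain transcription factor gene, held 17652 reads at chromosome 2 from 18820550 to 18820691, inside the gene. SIG4 (AT5G13730), which encodes a sigma factor of the plastid RNA polymerase, had 15076 reads beside it at chromosome 5 from 4431228 to 4431362. BBX28 (AT4G27310), a B-box zinc finger gene, had 14201 reads beside it at chromosome 4 from 13674983 to 13675111. A region of 684 bp on chromosome 3 from 5124719 to 5125403 with 12492 reads had no protein-coding gene within 1 kb, and AT3G15220 was the nearest. The tenth region, on chromosome 1 from 27627822 to 27627961, held 10473 reads inside AT1G73470 and within 1 kb of AT1G73480. All 10 had a false discovery rate of 0 in the deposited list, as did 20 regions in all, and these ties were ranked by reads.

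Across the list, regions were narrow and differed widely in reads. The median length was 150 bp (quartiles 129 and 195), and 440 regions were longer than 500 bp. A region held a median of 194 reads (quartiles 71 and 616), from 17 to 26570. The 100 regions with the most reads held 14.0% of all reads in regions, and the 2245 ranked highest by false discovery rate held 71.9%. The authors' false discovery rate was 5% or less in 5788 regions (64.4%) and above 50% in 900 regions. Their density ran from 70.3 regions per Mb on chromosome 3 to 79.3 on chromosome 1. Regions with better support held more reads: the median was 431.5 reads at a false discovery rate of 5% or less and 55 above it.

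Clock genes were found near a region more often than other genes. Of the 32 members of the clock list, 20 had a region centred in the gene or within 1 kb of either end (62.5%, 95% Clopper-Pearson interval 43.7 to 78.9), against 7691 of all 27444 protein-coding genes (28.0%; one-sided Fisher's exact test, p = 1.35e-04 after Benjamini-Hochberg adjustment over the 11 lists). Among genes named as transcription factors alone the clock list did not pass (9 of 12, 75% against 45.6%, adjusted exact p = 0.115). That test leaves out members without such a name, LHY among them, so it does not cover all factors of the list. The best regions of the 20 clock genes with a region had a median rank of 152.5, against 3796 for all genes with a region. Of the 20, 18 were among the 2245 regions ranked highest. Beyond the genes above, LNK4 (AT5G06980) had 8062 reads, LHY (AT1G01060), the closest relative of CCA1, 7957 reads, and PRR7 (AT5G02810) 5777 reads. RVE8 (AT3G09600), an activator of evening genes, had 5500 reads, LNK2 (AT3G54500) 5460 reads and RVE7 (AT1G18330) 5040 reads. PRR5 also had a region inside the gene, at chromosome 5 from 8357910 to 8358326, with 5940 reads (5790 to 6093). CHE (AT5G08330), a TCP factor that binds the CCA1 promoter, had 3598 reads, LUX (AT3G46640), a member of the evening complex, 3252 reads and LNK1 (AT5G64170) 2753 reads. Reads were fewer at RVE2 (AT5G37260, 1991 reads), AT4G01280 (1830 reads), RVE1 (AT5G17300, 1464 reads), ZTL (AT5G57360, 1207 reads) and JMJ30 (AT3G20810, 1055 reads). AT1G01520 had 80 reads (63.4 to 99.6) at a false discovery rate of 1.84%, the weakest of the 20, and a region of 6578 reads (rank 66, chromosome 1 from 187898 to 188519) lay between 1 and 3 kb from it. RVE2, ZTL, JMJ30 and PRR5 likewise had a better-ranked region at that distance, with 1328, 338, 2352 and 26570 reads. Many of these regions also lay within 1 kb of another gene: LNK4 shared its region with AT5G06970, LHY with UMAMIT28, PRR7 with RHL2, RVE8 with AT3G09590, LNK2 with AT3G54510, RVE7 with AT1G18335, LUX with AT3G46630, LNK1 with AT5G64180, RVE2 with AT5G37250, AT4G01280 with AT4G01270, RVE1 with AT5G17305, ZTL with AT5G57370 and AT1G01520 with AGL28. With the nearest gene only, LUX and AT1G01520 had no region. No region lay within 1 kb of the other 12 members, which were TOC1, PRR3, ELF3, ELF4, BOA, FKF1, LKP2, LWD1, XCT, TIC, RVE4 and AT5G52660. ELF4, FKF1 and TIC had a region between 1 and 3 kb away, and that of FKF1 had a false discovery rate of 100%.

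**Figure D1:**
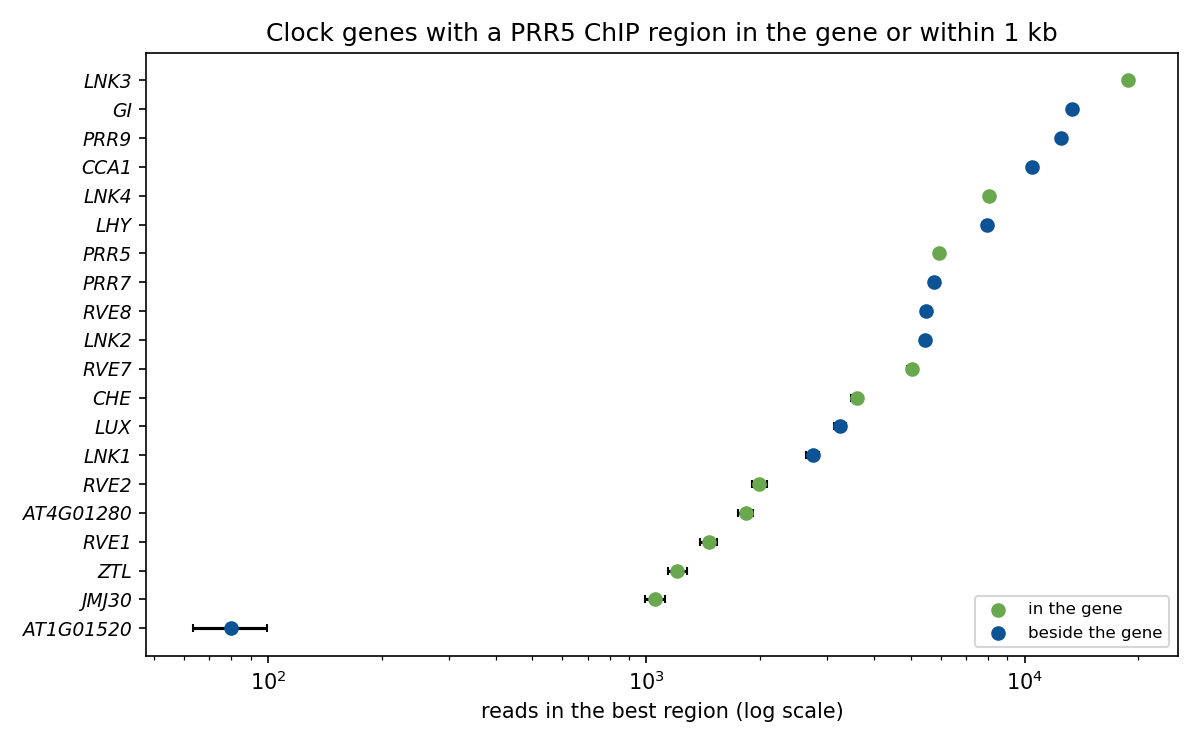
Reads in the best region of each of the 20 clock-list genes with a region in the gene or within 1 kb (x axis, log scale), coloured by whether the region centre lay in the gene or beside it; bars are 95% Poisson intervals, which cover counting error only and are narrower than most points. Reads run from 80 at AT1G01520 to 18796 at LNK3.

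Genes of light signalling, flowering time and the B-box family were likewise found near regions more often than other genes. Among members named as transcription factors alone, the light signalling and hypocotyl growth list did not pass (6 of 8, adjusted exact p = 0.211). Over all its members, 15 of 22 had a region (68.2%, 45.1 to 86.1, adjusted exact p = 2.30e-04). They included the phytochrome-interacting factor genes PIF5 (AT3G59060, 7432 reads) and PIF4 (AT2G43010, 2948 reads), the photoreceptor gene PHYB (AT2G18790, 4850 reads) and HY5 (AT5G11260, 2318 reads, also within 1 kb of OCP3), which encodes a bZIP factor of the light response. In the flowering list, 19 of 25 members had one (76%, 54.9 to 90.6; adjusted exact p = 4.81e-06). AT1G69570 had 3566 reads (1283 in the best region within 500 bp), COL1 (AT5G15850) 5227 reads in a region also within 1 kb of AT5G15853 and PCME and nearest to another gene, and the CDF genes CDF2, CDF3 and CDF1, whose Dof-type proteins repress CO, 1290, 1255 and 1294 reads, that of CDF1 also within 1 kb of AT5G62440. The regions at FLC, FLM and TSF had false discovery rates of 18.0%, 61.6% and 6.63%, that of FLM also lay within 1 kb of AT1G77090, and FT had none within 1 kb. Between 1 and 3 kb away FLM had a region at 0.0027% (360 reads) and FT one at 0.0033% (103 reads). Of 23 B-box zinc finger genes, 17 had a region (73.9%, 51.6 to 89.8; adjusted exact p = 2.37e-05), with 14201 reads at BBX28, 3722 at BBX29 (AT5G54470) and 2320 at BBX24 (AT1G06040), also within 1 kb of AT1G06045 and AT1G06050. Among the 2245 regions ranked highest, the counts were 13 light signalling, 11 flowering and 15 B-box genes.

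Photosynthesis, phenylpropanoid and hormone lists also passed the test. In the photosynthesis and chlorophyll list 19 of 25 members had a region (76%, 54.9 to 90.6; adjusted exact p = 4.81e-06), and 16 had one among the 2245 ranked highest. The test counts neighbouring members as independent genes, such as RBCS1B, RBCS2B and RBCS3B, whose regions lay on chromosome 5 from 15377779 to 15383525. LHCA1 (AT3G54890), of the photosystem I antenna, had 5808 reads (also within 1 kb of CXIP1), CHLH (AT5G13630), a subunit of magnesium chelatase, 5183 reads (also within 1 kb of PDAT), and LHCB1.1 (AT1G29920), which has close copies beside it whose reads can be shared, 2135 reads. In the phenylpropanoid and flavonoid list 11 of 15 had a region (73.3%, 44.9 to 92.2; adjusted exact p = 6.40e-04), with 1406 reads at C4H and 1404 at F3H, also within 1 kb of AT3G51230. In the auxin and gibberellin list it was 10 of 14 (71.4%, 41.9 to 91.6; adjusted exact p = 0.00145), led by the auxin receptor gene TIR1 (AT3G62980) with 4893 reads. In the abscisic acid list it was 10 of 16 (62.5%, 35.4 to 84.8; adjusted exact p = 0.00571), led by the phosphatase gene PP2CA (AT3G11410) with 3936 reads. Counting only regions outside genes gave an adjusted exact p = 0.156 for the auxin and gibberellin list and 0.0923 for the abscisic acid list.

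The cold response list passed narrowly, with 10 of 20 members (50%, 27.2 to 72.8; adjusted exact p = 0.0374). CBF1 (AT4G25490) and CBF2 (AT4G25470), which encode activators of cold-responsive genes, had 8604 and 6786 reads beside them, the first also within 1 kb of RS40. No region lay within 1 kb of CBF3, but the region beside CBF2 lay between 1 and 3 kb from CBF3. The assay does not tell which of these genes it acts on. Against random lists matched on gene length and on the space beside the genes, the adjusted p of the cold list was 0.0631. The starch list, with 6 of 13 members (46.2%, 19.2 to 74.9; adjusted exact p = 0.127), and the list of reference genes often used to normalise expression, with 6 of 12 (50%, 21.1 to 78.9; adjusted exact p = 0.0979), did not pass. All 6 starch genes had a region among the 2245 ranked highest, GBSS1 (AT1G32900) leading with rank 158 and 4985 reads, and with those regions alone both lists passed (adjusted exact p = 7.43e-04 for starch and 0.0169 for the reference genes). Of the reference genes, UBQ10 (AT4G05320) had 6553 reads, GAPC1 3681 (also within 1 kb of GLR1.1) and ACT7 1763. When only genes annotated as transcription factors were compared, of which 45.6% had a region against 28.0% of all genes, 2 of the 9 lists with such members passed, flowering (86.7%, adjusted exact p = 0.0109) and B-box (73.9%, 0.0236).

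**Figure D2:**
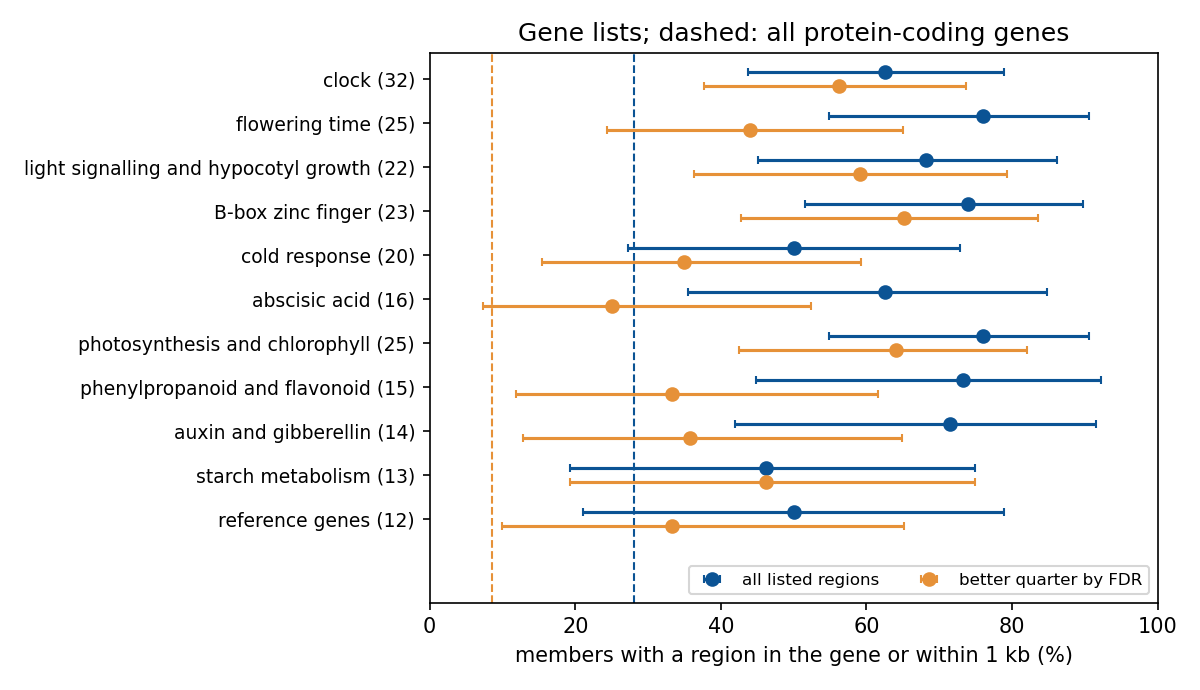
Share of each gene list's members with a region in the gene or within 1 kb (x axis, percent; number of members in brackets), for all listed regions (blue) and for the 2245 ranked highest by false discovery rate (orange); bars are 95% Clopper-Pearson intervals and dashed lines the shares of all protein-coding genes, 28.0% and 8.60%. The clock list stands at 62.5% and 56.2%.

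Among genes whose RefSeq symbol or synonyms name a transcription factor family, the 10 ranked highest outside the first 10 regions came from several families. LHY, at rank 14, has no such name in the table and was not counted. The 10 were PIF5, NF-YA4 (AT2G34720, 4177 reads), CBF1, BBX29, ARF2 (AT5G62000, an auxin response factor gene, 7344 reads), CBF2, AGL44 (AT2G14210, a MADS-box gene, 3764 reads), NF-YB2 (AT5G47640, 7811 reads), PIF4 and PRR7. In PIF5 and PIF4 the region centre lay inside the gene, and at the other 8 it lay beside it.

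Regions with the strongest support lay beside genes more often than chance. Of the 2245 regions ranked highest, 30.5% were centred outside protein-coding genes but within 1 kb of one, against 20.4% of random placements on the same chromosomes (n = 2245 regions, two-sided p = 0.002, the smallest that 1000 placements can give). Of these regions 47.8% were centred in genes, against 54.1% (n = 2245, p = 0.002), and 21.6% lay farther away, against 25.5% (p = 0.002). Over all 8983 regions the shares were 23.6% beside genes against 20.4% (n = 8983, p = 0.002), 51.6% in genes against 54.2% (p = 0.002) and 24.8% farther away against 25.4% (p = 0.168). The excess of all regions beside genes was not found when each was moved at random within 20 kb (23.6% against 23.6%, n = 8983, p = 0.923), and it turned into a deficit within 500 bp (12.0% against 13.2%, p = 0.002) and when all annotated genes were counted (23.6% against 24.8%, p = 0.016). With placement within 20 kb the 2245 ranked highest still stood at 30.5% against 23.5% (n = 2245, p = 0.002). The share farther away depended on the placement: moved within 20 kb, it was above random for all regions (24.8% against 19.0%, n = 8983, p = 0.002) and for the 2245 ranked highest (21.6% against 16.2%, n = 2245, p = 0.002). The deficit in genes lay away from their ends. Of all regions, 1162 were centred 200 to 400 bp inside a gene end, against 744 in placements within 20 kb. From 1000 to 1500 bp inside it was 412 against 834. For the 2245 ranked highest, only the 200 bp next to the end held more than random (274 against 202).

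The share of regions within 400 bp outside genes fell with weaker support. That sequence held 392 of the 2245 regions ranked highest (17.5%, 95% Clopper-Pearson interval 15.9 to 19.1), 259 of the 2246 ranked next (11.5%, 10.2 to 12.9) and 245 of the 4492 ranked lowest (5.45%, 4.81 to 6.16). Random placement within 20 kb gave 12.9%, 13.0% and 12.6%. The excess of the 2245 ranked highest lay in the first 200 bp (265 against 165 random), with none from 200 to 400 bp (127 against 124). The distance of 400 bp was chosen after the positions had been seen, so no p is given.

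**Figure D3:**
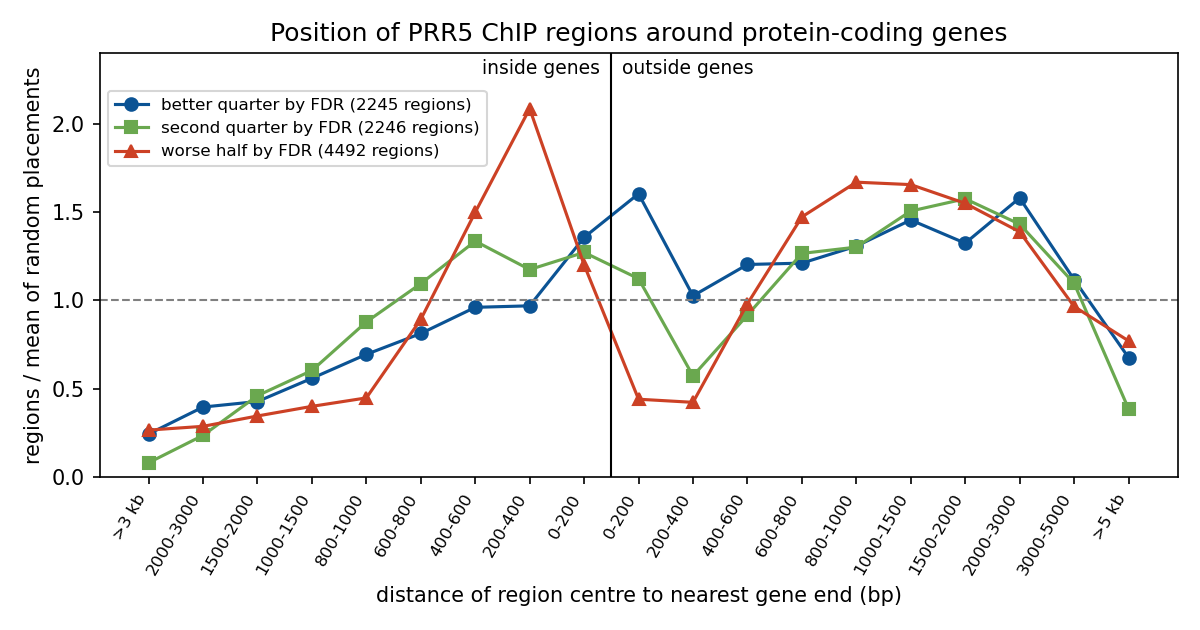
Number of regions divided by the mean of 1000 random placements within 20 kb (y axis), by distance of the region centre to the nearest end of a protein-coding gene (x axis, bp, unequal bins; left of the line inside genes), for the 2245 regions with the lowest false discovery rates (blue circles), the 2246 next (green squares) and the 4492 with the highest (red triangles). In the first 200 bp outside genes the ratio is 1.60 for the first set and 0.440 for the last.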

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

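All tests in this part were chosen after the data had been seen.

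The split of reads by strand was not part of any comparison, and in 84 regions (0.935% of 8983) forward and reverse counts were unequal in an exact binomial test with Benjamini-Hochberg adjustment, which singled them out for a closer look. The squared difference of the strand counts divided by the reads averaged 1.54 over all regions, where independent reads give 1, 1.01 in the eighth of the list with the fewest reads and 2.52 in that with the most. The test and the intervals here treat reads as independent and cover counting error only, so regions with many reads are called too readily. The region with the lowest adjusted p, 2914 bp on chromosome 5 from 11867840 to 11870754 with AT5G32440 as the nearest gene, had 44.1% forward reads of 8473 (43.0 to 45.1%). On chromosome 3 from 20763016 to 20763207, nearest to AT3G55960, it was 30.4% of 372 reads (25.7 to 35.3%), and at the region with the most reads, nearest to PRR5, 51.8% of 26570 (51.2 to 52.4%).

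The excess of regions at 9 gene lists was weighed against technical explanations. Longer genes with more space beside them could hold more regions by chance, so each list was compared with 10000 random lists matched on gene length and neighbouring space. This alone does not account for the excess at 8 of the 9, whose adjusted permutation p ran from 0.0004 to 0.0315. It stays open for the cold list, at 50% against a mean of 30.7% (adjusted permutation p = 0.0631). With the 2245 regions ranked highest the cold list was past the threshold (adjusted permutation p = 0.0013). The abscisic acid list was not (adjusted permutation p = 0.0818). The starch list was also past the threshold with these regions (adjusted permutation p = 0.0013). So were the reference genes (33.3% against a mean of 10.5%, adjusted permutation p = 0.0332). Passing against matched lists with these regions was therefore not limited to the 9 lists. Chromatin of strongly transcribed genes may be pulled down whatever the protein, and this stays open: among the 2245 regions ranked highest, the reference genes had a share of 33.3% (4 of 12), against 49.0% (94 of 192) in the lists that passed (two-sided Fisher's exact p = 0.378) and 8.60% of all genes. So few genes do not decide it. A pull-down from plants without the tagged protein was not analysed here. Binding of PRR5 remains a hypothesis for these lists as groups.

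The weakly supported regions avoided the sequence just outside genes. Of the 4492 regions ranked lowest, 5.45% lay within 400 bp outside a gene, and 95% of random placements within 20 kb gave 11.7 to 13.6%. Among the 1688 of them with no other region within 5 kb the share was 6.64%, against 10.6 to 13.6%. Crowding by stronger regions alone therefore does not account for the low share. The random placements were not kept 5 kb from other regions, so a part played by crowding stays open. An uneven input, with more reads just outside genes and so a higher bar there, is a candidate explanation that was not tested, as no input counts per region were used. No biological explanation was tested.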

How the results depend on the processing

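The alternatives that changed a result below, other than the lower-ranked regions left out, any overlap in place of the centre, all annotated genes and the background of transcription factor genes, were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Motif settings, strand-based windows, ratios of ChIP to input and the setting without organelle chromosomes were not run; the list holds no organelle regions. Library depth is unknown, so it cannot be said what regions were missed.

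The number of regions was 4491 or 2245 by the share of the list kept, and 5788 at a false discovery rate of 5% or less; merging changed none. The share in genes stayed below random placement in the 6 alternatives that can alter it; the 500 bp and 3 kb windows cannot. The share beside genes turned to a deficit with all annotated genes (23.6% against 24.8%, n = 8983, p = 0.016) and within 500 bp (12.0% against 13.2%, p = 0.002), and was level with placement within 20 kb (23.6%, p = 0.923). The share farther away, level with random placement at first (24.8% against 25.4%, n = 8983, p = 0.168), was an excess within 20 kb (against 19.0%, p = 0.002), with all annotated genes (18.0% against 11.1%, p = 0.002) and with 500 bp (36.4% against 32.6%, p = 0.002), and a deficit in the other 5. These causes were not tested.

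Of 97 settings for single lists, 78 left the call as it was. Against transcription factor genes 2 of 9 lists passed; the background share is higher there (45.6% against 28.0%) and fewer members remain. The shares were 75% for clock (9 of 12, adjusted exact p = 0.115), 75% for light signalling (0.211), 60% for cold (0.538), 100% for photosynthesis (0.312) and 80% for phenylpropanoid (0.247), and 0% for abscisic acid (0 of 2) and for auxin and gibberellin (0 of 1). Only members whose symbol or synonyms name a transcription factor family were counted. The 10 abscisic acid and the 10 auxin and gibberellin members with a region, among them ABI5, RGA and GAI, lacked such a name. The 0% therefore does not describe these lists. The cold list was also not past the threshold within 500 bp (40%, 0.0606), within 3 kb (55%, 0.332), outside genes (20%, 0.146), with the nearest gene (40%, 0.126) and against matched lists (50%, 0.0631). Outside genes the abscisic acid list (25%, 0.0923) and the auxin and gibberellin list (21.4%, 0.156) did not pass. The starch list passed at 46.2% with 4491 regions (0.0122), 2245 regions (7.43e-04) and the 5% threshold (0.0337), and the reference genes at 33.3% with 2245 regions (0.0169) and 58.3% with the nearest gene (0.0225). The cause was not tested for these.

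Of 48 named genes, 42 had the same best region within 500 bp, 1 had another (AT1G69570, 1283 reads in place of 3566) and 5 had none (GI, CBF1, AT1G01520, AT2G46780 and AT1G73480). Within 3 kb 5 had another, among them PRR5 with 26570 reads. With the nearest gene only, 6 had none (LUX, COL1, AT1G01520, BUG22, PSI-P and AT1G73480) and 2 another (PRR5 with 26570 reads, AT2G46780 with 961 in place of 12486), and with regions outside genes only, 21 had none.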

Other observations

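All tests in this part were chosen after the data had been seen, except that of tRNA gene arrays, which was written before its result.

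Genes annotated as transcription factors had regions more often than other genes: 485 of 1063 (45.6%) against 27.3% (odds ratio 2.23, two-sided Fisher's exact p = 1.22e-35), and 180 (16.9%) against 8.26% with the 2245 regions ranked highest (odds ratio 2.26, p = 5.28e-19). Neither comparison was matched on gene length or neighbouring space, so a part played by these stays open. Gene families, taken as 239 symbol stems with at least 10 members, were then tested with those 2245 regions, and 5 passed after Benjamini-Hochberg adjustment, 4 of them also against random lists matched on gene length and neighbouring space. Over all listed regions 14 stems passed, 8 of them also against matched lists. The B-box stem led with 18 of 31 genes (adjusted exact p = 1.03e-09), and overlaps the list of the report. The WRKY genes, a family of factors in defence and stress responses, had 16 of 72 (22.2%, 95% Clopper-Pearson interval 13.3 to 33.6; adjusted exact p = 0.0160) and did not pass against the matched lists (adjusted permutation p = 0.117), but did over all listed regions (39 of 72, adjusted permutation p = 0.0329). Of these WRKY47 (AT4G01720) had 1981 reads, WRKY40 (AT1G80840) 3747, WRKY7 (AT4G24240) 2018 and WRKY70 (AT3G56400) 2153. The IAA stem, of auxin response repressors and a few genes with such a synonym, had 10 of 32 (adjusted exact p = 0.0143; matched, permutation p = 0.0279, and 0.150 over all listed regions), among them IAA2 (AT3G23030) with 1388 reads and IAA16 (AT3G04730) with 3578. The PKS stem, with 8 of 13 (adjusted exact p = 3.06e-04), pools phytochrome kinase substrate genes such as PKS4 (AT5G04190, 1433 reads) and PKS2 (AT1G14280, 2650 reads) with protein kinase genes such as CIPK15 (AT5G01810, 8805 reads). The CP stem, with 7 of 14 (adjusted exact p = 0.00547), also pools unrelated genes. Over all listed regions it did not pass against the matched lists (adjusted permutation p = 0.0597).

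Among genes that do not encode proteins, types differed. Region centres lay in lncRNA genes 414 times, against 153 in random placements within 20 kb (n = 8983 regions, 2.71-fold, adjusted p = 0.003 over 6 types), in snRNA genes 8 times against 1.19 (adjusted p = 0.003) and in pseudogenes 125 times against 292 (0.428-fold, adjusted p = 0.003). At a false discovery rate of 5% or less the ratios were 2.70, 7.57 and 0.169. For miRNA genes (7 against 4.98, n = 8983, adjusted p = 0.474) and snoRNA genes (1 against 2.73, adjusted p = 0.474) no difference was detectable at these counts.

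Of all regions, 35 were centred in tRNA genes, against 3.31 in random placements within 20 kb (n = 8983, 10.6-fold, adjusted p = 0.003). They do not come from a few arrays, since 5.71% of them (2 of 35) lay within 50 kb of another. Regions with a false discovery rate above 5% do not account for the excess either. At 5% or less there were 25 of the 35, against 2.14 random ones (95% range 0 to 5). Strong support was rare: among the 2245 regions ranked highest were only those in AT1G12510 and AT4G14345, at ranks 1108 and 1943. The 35 held a median of 144 reads, against 194 over all regions. Reads shared between tRNA gene copies, and a pull-down of strongly transcribed genes whatever the protein, are possible explanations that were not tested, and no biological explanation was tested. The best of these regions, in AT1G12510 on chromosome 1 from 4266978 to 4267140, had 1025 reads and rank 1108.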
